A study of Mus musculus with 4 samples.

How the data were processed

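RNA from mouse hearts was sequenced in 4 libraries, 2 at 8 weeks and 2 at 12 months. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these samples. Per the labels, poly(A) RNA with an integrity number above 7 was made into strand-specific libraries by the dUTP method and read in pairs on a NovaSeq 6000. The submitters' processing notes list cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR with the mouse genome build GRCm38. The roles and settings of these tools, the treatment of reads that map to several places and the strand setting of the counting are not given in the sources used here.

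The deposited table holds, per the file headers, an FPKM value (fragments scaled by transcript length and library size) and an estimated count per gene for each library, with gene coordinates and GO and KEGG terms. The FPKM values were made by the authors with 1 length per gene, and their sums differ between libraries. The deposited expected counts are whole numbers already: in a check on 18 values they exceeded the number implied by the FPKM by 0.037 to 0.805, so fractional estimates had been rounded up. The table has 28723 genes, 0 of them without a name, and 51 symbols stand on 2 or more entries, which were kept apart. Genes were kept for testing when their mean FPKM over the 4 libraries was at least 1, which left 12027.

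The test planned from the labels was limma on log2(FPKM + 1). Because the table also holds counts, edgeR's quasi-likelihood test was used in its place, as the plan provided, and the planned test was run as an alternative. The test (edgeR 4.0.16 in R 4.3.3) used TMM scaling, an intercept and age, no replicate block, and a two-sided contrast of 12 months minus 8 weeks. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. The common dispersion was 0.0243, with 2 residual and 4.03 prior degrees of freedom. Log2 fold changes are given ± SE, which is the size of the log2 fold change divided by the square root of the F statistic, and FPKM as mean ± SD. On data simulated from these counts the fit recovered 38.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 92.4% of those changed 4-fold, with 16 false calls among 151. The simulation changed 67, 67 and 66 genes by these folds, far fewer than the 4520 called in the data, so its rates need not hold for them. Where a whole group had no count, a fold is a lower bound that sets 3 counts over that group. Intervals and floors cover counting error only.

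Gene lists for 49 pathways and cell types, the rule for named genes and most alternatives were chosen before the data were examined. The 47 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 47 lists, and beside it with camera at an estimated correlation and with fry. Lists share some genes. Named genes are the 10 largest rises and the 10 largest falls among called genes whose ages did not overlap, up to 4 members of each list with the smallest p, the 5 most abundant called genes in each direction and a fixed set of check genes. The rule left out predicted and pseudogene symbols, and some genes that it names are not reported here. Myl7, Nr2f2, Gja5, Wt1, Tbx18, Fabp4, Pparg, Vwf, Cd36, Npr3, Plvap, Ndufs1, Sdha, Uqcrc2 and other members named because they moved against their list fall outside that rule, and these genes were named after the values were seen. The second lists of atrial and fat-cell genes fall outside it too, and were written after the results of the first lists were seen but before their own values were. Of the 224 named genes, 92 overlap another gene of the table, 43 on the same strand and 64 on the opposite strand, so reads may be shared between them. GO and KEGG terms of 10 to 500 genes were tested with a one-sided hypergeometric test among tested genes that carry a term (10827 for GO, 4538 for KEGG), adjusted for each direction and source.

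Transcript length and GC content came from the longest listed transcript found in the GENCODE reference, for 12020 of the 12027 tested genes (99.94%). To remove their trends, a smooth fit per library (mgcv 1.9.3, 8 basis functions) was added to the offsets. Other alternatives changed the expression minimum (0.1, 5 or none), the pseudocount, the scaling, the variance model and the threshold, or left out each library in turn. After the data were seen, DESeq2 1.42.0, removal of length or GC trends, and leaving out mitochondrially encoded genes with their 7 nuclear copies on chromosome 1 were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Nothing in the count table was left out for lack of a sample: 0 count or FPKM columns had no label.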

Results

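Gene expression was measured by sequencing poly(A)-selected RNA from whole hearts of untreated C57BL/6J mice that the labels give as wild type. There were 4 libraries, 2 from mice aged 8 weeks (young) and 2 from mice aged 12 months (aged). Young replicates 1 and 2 held 52866260 and 63828074 estimated counts, and aged replicates 1 and 2 held 55411355 and 51328364. A gene without a count may therefore lie anywhere up to 0.047 to 0.0585 CPM, depending on the library (3 counts of its total), a floor that covers counting error only. Mitochondrially encoded genes took 27.08% of the counts in young replicate 1 (95% Wilson interval 27.07% to 27.09%), 27.26% in young replicate 2 (27.25% to 27.27%), 23.71% in aged replicate 1 (23.7% to 23.72%) and 23.25% in aged replicate 2 (23.24% to 23.26%). The 7 nuclear copies of mitochondrial genes on chromosome 1 took a further 7.53% and 7.437% of the counts in young replicates 1 and 2. In aged replicates 1 and 2 they took 5.395% and 5.574%. Reads may be shared between these copies and the mitochondrial genes, which the intervals do not cover. Across genes, which are not independent replicates, the log2 FPKM values correlated with Pearson's r of 0.991 between the young libraries, 0.968 between the aged libraries and 0.937 to 0.95 between ages. The first principal component held 63.7% of the variance and set the ages apart. The second held 27.2% and set aged replicate 1 (-35.93) apart from aged replicate 2 (26.13).

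The comparison asks how gene expression in the heart differs between aged and young mice. At 12 months, most tested genes that mark atrial muscle (10 of 12), the mesothelial covering of the heart (9 of 11) and fat cells (13 of 17) were higher than at 8 weeks, many of them several-fold. A rise helps a gene to pass the expression minimum, which is a mean over all 4 libraries. In young hearts, 10 of the 12, 5 of the 11 and 11 of the 17 averaged at least 1 FPKM, so these shares are partly set by the minimum. Part of the genes of calcium handling (11 of 23), fatty acid oxidation (13 of 27), the TCA cycle (15 of 25) and complement (9 of 17) rose, with smaller list medians. Pck1, an enzyme that fat cells use to make glycerol for fat storage, rose from 0.391 ± 0.0425 to 21.6 ± 0.448 FPKM (mean ± SD, n = 2 libraries each). Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose from 943 ± 31.3 to 2033 ± 108 FPKM (n = 2 each). Most endothelial markers (21 of 26), complex I genes (33 of 36), ribosomal protein genes (24 of 41) and interferon-stimulated genes (21 of 34) fell at 12 months. The tests that set all these gene lists against other genes were not passed with an estimated correlation (adjusted p from 0.449 to 0.665). That setting leaves 2 residual degrees of freedom, so failing it says little about a list. The preset correlation of 0.01 lies far below the estimate for complex I (0.666), ribosomal protein (0.531) and interferon-stimulated genes (0.521). It lies near the estimate for endothelial markers (0.004). Small p-values at the preset may therefore overstate the evidence for lists whose genes move together. Egfl7, a protein secreted by endothelial cells, fell from 52.5 ± 1.74 to 17.0 ± 0.126 FPKM, and Ndufs6, a subunit of respiratory complex I, fell from 103 ± 4.65 to 45.4 ± 5.68 FPKM (n = 2 each).

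Of 12027 genes tested with edgeR, 2416 rose and 2104 fell at 12 months, and 383 and 311 of them did so by at least 2-fold. In every called gene, both libraries of one age lay above both of the other. That held for 73.3% of all tested genes, against 33.33% if the ages were exchangeable. The fit without young replicate 1 called 1187 genes higher and 890 lower, and the fit without young replicate 2 called 1259 and 1048. When the FPKM of each library were rescaled to one sum and tested with limma, 3820 genes were called higher and 1100 lower, so the balance between rises and falls depends on how the libraries are scaled.

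**Figure D1:**
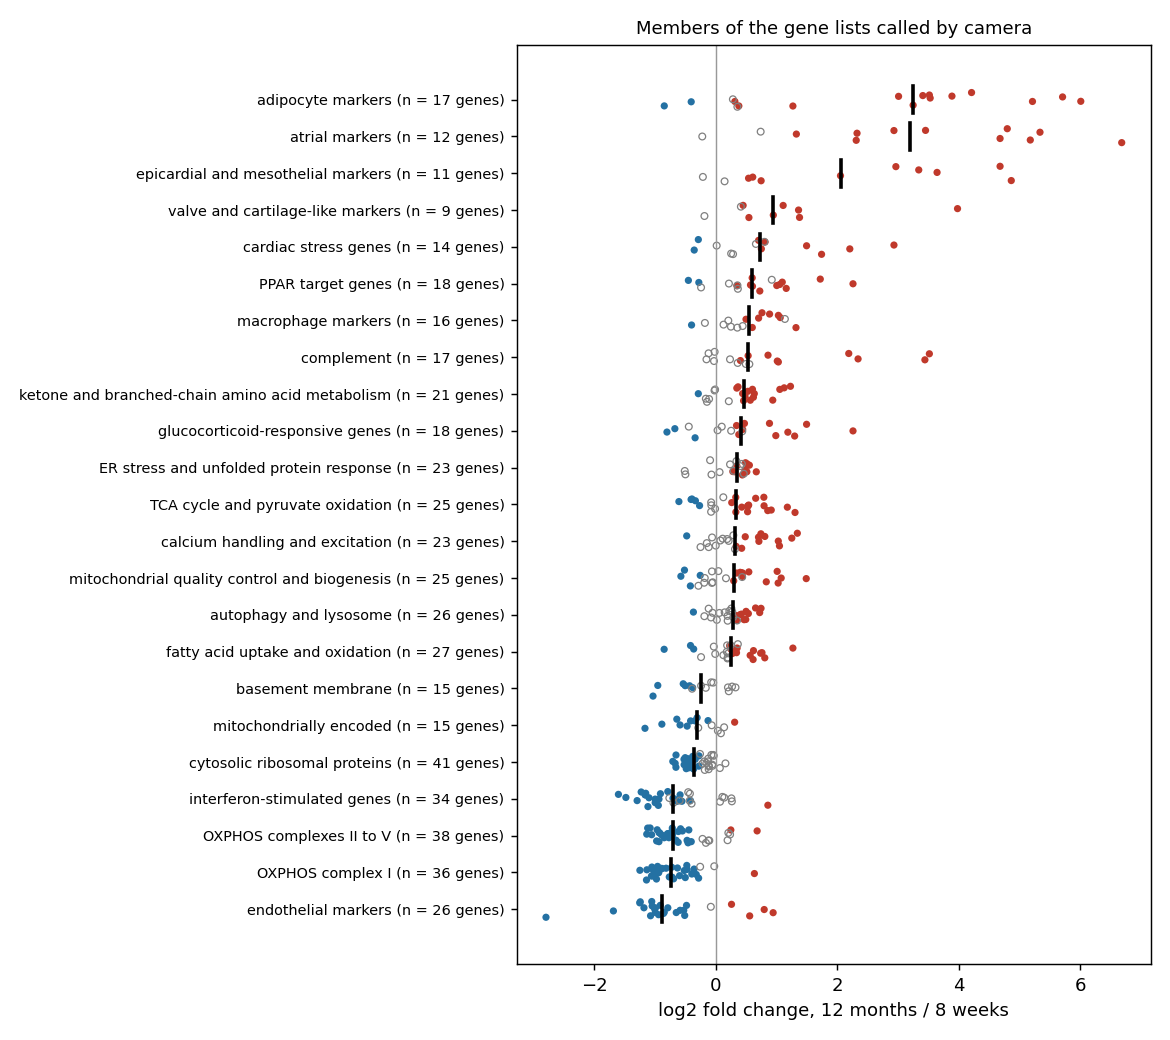
Each point is 1 gene of a gene list that the camera test called, placed by its log2 fold change (12 months over 8 weeks) on the horizontal axis, with 1 list per line. Filled points passed the gene test (red higher, blue lower), open points did not, and black bars mark list medians, which run from -0.89 for endothelial markers to 3.25 for adipocyte markers.

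Of the 4 largest rises outside the immunoglobulin genes, Bmp10 and Mybphl mark atrial muscle and Ucp1 marks brown fat. Of 12 atrial markers tested, 10 rose and none fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 3.20 (camera adjusted p = 1.21e-11; adjusted p = 0.449 with an estimated correlation). Sln, the atrial inhibitor of the calcium pump, rose from 2.21 ± 1.51 to 91.7 ± 23.3 FPKM (log2 fold change 5.34 ± 0.47, SE). Its log2 fold change was 4.74 without young replicate 2 and 6.27 without young replicate 1. Mybphl, a myosin-binding protein of atrial muscle, rose from 1.06 ± 0.589 to 70.4 ± 35.5 FPKM (log2 fold change 6.02 ± 0.53, between 5.34 without aged replicate 1 and 6.71 without young replicate 1). The atrial light chain Myl7 was at 29.8 and 7.86 FPKM in the young libraries and at 927 and 484 FPKM in the aged. Bmp10, a growth factor made in the atria, had a log2 fold change of 6.68 ± 1.85 that rested on aged replicate 2, with 7.80 FPKM there and 0.169 FPKM in aged replicate 1. Its log2 fold change was 2.19 without aged replicate 2, and its call was lost without young replicate 1 (adjusted p = 0.151) or young replicate 2 (adjusted p = 0.137). The atrial markers Nr2f2 (-0.22, adjusted p = 0.218) and Gja5 (0.74, adjusted p = 0.0906) did not pass. Of 11 epicardial and mesothelial markers, 9 rose (9 adjusted over the list alone), with a median of 2.06 (camera adjusted p = 6.56e-08; adjusted p = 0.449 with an estimated correlation). Of these 11, 5 averaged at least 1 FPKM in young hearts, and the others entered the test through their aged values. Upk3b, a membrane protein of mesothelial cells that was also on the atrial list, rose from 0.306 ± 0.154 to 8.38 ± 0.262 FPKM. Its log2 fold change was 4.68 ± 0.31, between 4.27 without young replicate 1 and 5.32 without young replicate 2. Lrrn4 rose 29.2-fold. The epicardial transcription factors Wt1 (-0.21, adjusted p = 0.317) and Tbx18 (0.15, adjusted p = 0.524) did not pass.

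Of 17 adipocyte markers, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 3.25 (camera adjusted p = 1.86e-15; adjusted p = 0.449 with an estimated correlation). Of these 17, 11 averaged at least 1 FPKM in young hearts, and the others entered the test through their aged values. Pck1, on chromosome 2 at 173153048 to 173159273 of GRCm38, rose 52.4-fold (log2 fold change 5.71 ± 0.12, adjusted p = 7.59e-05, the smallest of all genes). Plin1, a coat protein of fat droplets, rose from 0.106 ± 0.0277 to 4.27 ± 0.157 FPKM. Cidec, another droplet protein, had a log2 fold change of 4.21 ± 0.39, between 3.72 without young replicate 2 and 4.90 without young replicate 1. Ucp1, the heat-producing protein of brown fat, was at 55.2 FPKM in aged replicate 1 and 10.2 FPKM in aged replicate 2, against a young mean of 0.497 ± 0.293, and its log2 fold change of 6.01 ± 0.97 was 4.27 without aged replicate 1. The list median was 2.65 without young replicate 2. The 2 members that fell were Fabp4, which was also on the endothelial list, from 154 ± 19.5 to 89.0 ± 8.08 FPKM, and Pparg (-0.40, adjusted p = 0.0449). Of 9 valve and cartilage-like markers, 7 rose (7 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 0.00551; adjusted p = 0.661 with an estimated correlation), led by Cilp2, a cartilage matrix protein (3.98 ± 0.35). The valve list lost its call when FPKM were rescaled to one sum (adjusted p = 0.0669). Melanocyte antigen Mlana rose (log2 fold change 6.49 ± 0.96), with counts of 5 and 0 in the young libraries and 318 and 141 in the aged, so the size of its change is uncertain.

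**Figure D2:**
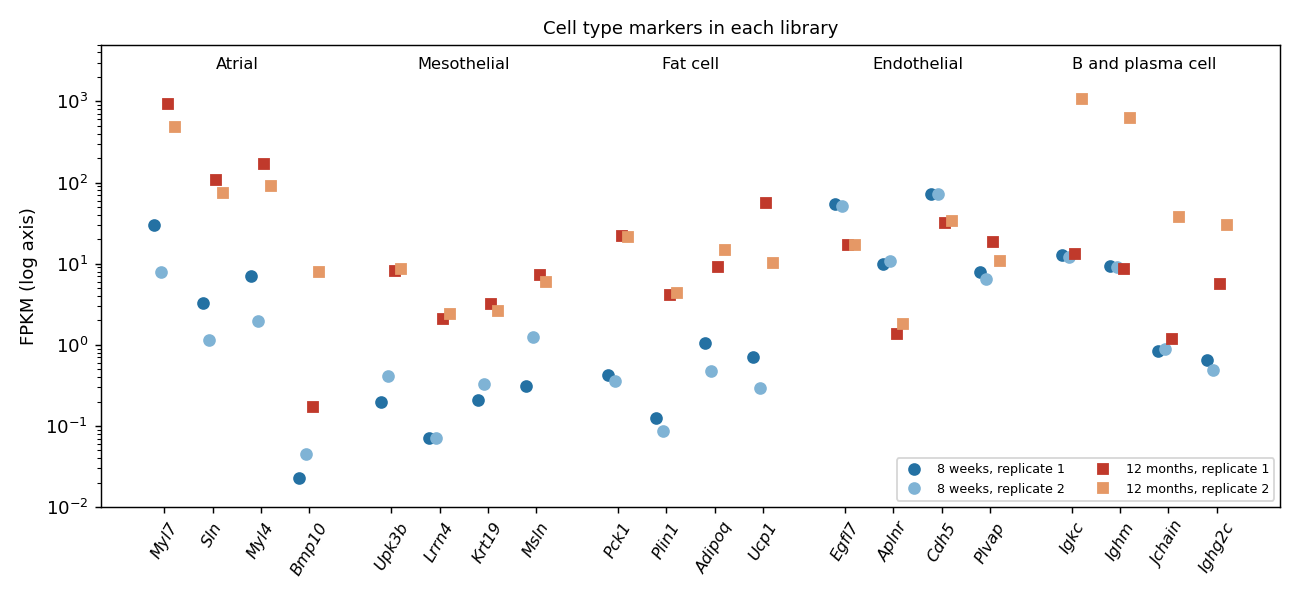
FPKM of single genes on a log axis, with 4 markers per cell type on the horizontal axis and 1 symbol per library (circles 8 weeks, squares 12 months). Atrial, mesothelial and fat-cell markers lie higher in both aged libraries, while Igkc lies at 1057 FPKM in aged replicate 2 and at 12.1 to 13.3 FPKM in the other libraries.

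Of 26 endothelial markers, 21 fell and 4 rose (21 and 4 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 4.83e-18; adjusted p = 0.449 with an estimated correlation). Aplnr, the apelin receptor, on chromosome 2 at 85136225 to 85139923, had the largest fall of all named genes, from 10.4 ± 0.544 to 1.57 ± 0.319 FPKM (log2 fold change -2.79 ± 0.15). Egfl7 had a log2 fold change of -1.68 ± 0.07, the receptor kinase Tie1 of -1.24 ± 0.08, and the junction protein Cdh5 fell from 71.7 ± 0.459 to 32.9 ± 1.32 FPKM. The members that rose were Vwf, the clotting protein von Willebrand factor (0.56 ± 0.13), the fatty acid transporter Cd36 (0.26 ± 0.07), the natriuretic peptide receptor Npr3 (0.80 ± 0.24) and Plvap, a protein of fenestrated endothelium (0.95 ± 0.27). Among the 10 largest falls of all genes were also the transcription factors Tcf15 (-1.80 ± 0.13), Hlx (-1.97 ± 0.15) and Lhx6 (-1.83 ± 0.18), together with Exoc3l (-1.89 ± 0.20), Apol10b (-1.99 ± 0.21) and the spliceosomal Snrpe (-1.86 ± 0.26). The other 3 were the microRNA hairpins Mir6942, Mir1898 and Mir6999, which lie inside host genes on the same strand, so their values are uncertain, and each lost its call without young replicate 1 (adjusted p = 0.0799, 0.0819 and 0.0769).

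Of 15 basement membrane genes, 6 fell and none rose (6 and 0 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.0319; adjusted p = 0.708 with an estimated correlation). Agrn, the proteoglycan agrin, and the laminin chain Lama5 had log2 fold changes of -1.03 ± 0.08 and -0.95 ± 0.10. That list was no longer called without young replicate 2 (median -0.30, adjusted p = 0.0585) or aged replicate 2 (median -0.16, adjusted p = 0.224), nor in the limma fit of log2(FPKM + 1) (adjusted p = 0.0668). Of 20 pericyte and smooth muscle markers, 8 fell and 3 rose (camera adjusted p = 0.0931, median -0.05). The list was called lower without young replicate 1 (median -0.12, adjusted p = 0.0324) and with a mean of at least 5 FPKM (median -0.62, adjusted p = 0.0261). The pericyte genes Vtn (-1.37 ± 0.12), Kcnj8 (-0.95 ± 0.11) and Rgs5 (-0.77 ± 0.09) were among those that fell, and the members that rose were the smooth muscle genes Cnn1 (1.98), Tagln (0.92) and Myocd (0.68). Fibroblast markers (median 0.13; 3 of 22 rose and 2 fell; camera adjusted p = 0.424) and Schwann and neuronal markers (median -0.06, mean 0.01; 1 of 11 rose; camera adjusted p = 0.843) were not called.

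Of 36 complex I genes, 33 fell and 1 rose (34 and 1 adjusted over the list alone), with a median of -0.74 (camera adjusted p = 1.06e-21; adjusted p = 0.479 with an estimated correlation). Ndufs6 (-1.25 ± 0.10), Ndufa13 (-1.06 ± 0.09) and Ndufa5 (-1.05 ± 0.07) were among the 4 members with the smallest p, and Ndufs1, the largest subunit of the complex, was the member that rose (0.64 ± 0.07). Of 38 genes of complexes II to V, 29 fell and 2 rose (29 and 5 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 1.62e-13; adjusted p = 0.639 with an estimated correlation). Uqcrq of complex III fell from 130 to 61.6 FPKM (log2 fold change -1.14 ± 0.08), and Atp5e of the ATP synthase had a log2 fold change of -1.12 ± 0.07. The members that rose were Sdha, the catalytic subunit of complex II, from 166 to 277 FPKM (0.68 ± 0.07), and Uqcrc2 (0.25 ± 0.07), and 7 more did not pass. Of 15 mitochondrially encoded genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00843; adjusted p = 0.477 with an estimated correlation). The ribosomal RNA mt-Rnr1 (-1.16 ± 0.09) and mt-Co2 (-0.59 ± 0.05) fell, and mt-Nd4l was the member that rose (0.31 ± 0.09), with its call lost without young replicate 1 (adjusted p = 0.205). The mitochondrially encoded list had a median of -0.17 with the transcript length trend removed, and was then not called (adjusted p = 0.12).

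Of 41 cytosolic ribosomal protein genes, 24 fell and none rose (25 and 0 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 9.68e-06; adjusted p = 0.665 with an estimated correlation). Rpl30 (-0.71 ± 0.07) and Rplp2 (-0.65 ± 0.07) had the smallest p. The median moved to -0.22 with the length trend removed (adjusted p = 0.00452). Fold changes followed transcript length over all tested genes, with a median of -0.22 among the 2405 genes with the shortest transcripts and of 0.08 among the 2402 with the longest. The median length was 1026 nt for complex I genes, 1232 nt for complexes II to V, 1128 nt for ribosomal protein genes and 3096 nt for all tested genes. They followed GC content as well, with a median of 0.09 among the 2404 genes with the lowest GC content and of -0.15 among the 2404 with the highest.

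**Figure D3:**
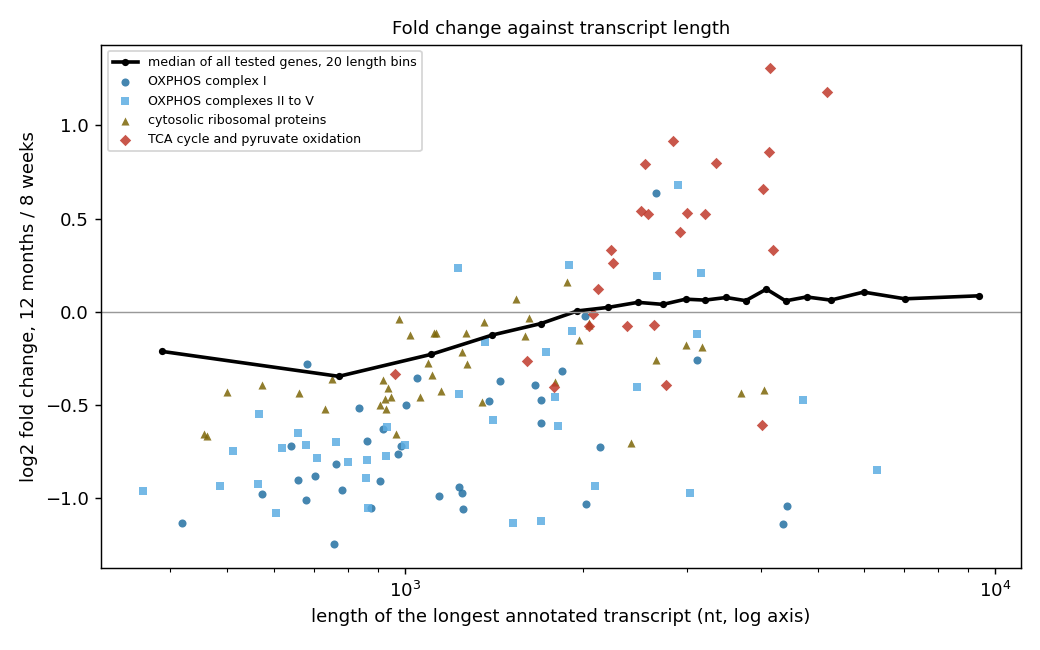
Log2 fold change (12 months over 8 weeks) against the length of the longest annotated transcript in nt on a log axis, with 1 point per gene of 4 lists and a black line for the medians of all tested genes in 20 length bins. Complex I genes (median -0.74) lie mostly below the line, and genes of the citric acid cycle (median 0.33) mostly above it.

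Of 25 genes of the citric acid (TCA) cycle and pyruvate oxidation, 15 rose and 5 fell (15 and 5 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00535; adjusted p = 0.639 with an estimated correlation), with the smallest p for the pyruvate dehydrogenase subunit Pdha1 (0.91 ± 0.07) and the dehydrogenase Ogdh (0.86 ± 0.08). Mpc1 and Mpc2, which form the mitochondrial pyruvate carrier, fell (-0.33 and -0.61), as did Mdh2, Idh2 and Suclg1. Of 27 genes of fatty acid uptake and oxidation, 13 rose and 3 fell (17 and 4 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00853; adjusted p = 0.449 with an estimated correlation). The fatty acyl-CoA synthetase Acsl1 (1.27 ± 0.08) and the trifunctional protein subunits Hadha (0.81 ± 0.08) and Hadhb (0.76 ± 0.07) had the smallest p of that list, and Etfb (-0.85), Eci1 and Slc27a1 fell. Of 18 PPAR target genes, 11 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.000121; adjusted p = 0.606 with an estimated correlation), among them the uncoupling protein Ucp2 (1.01 ± 0.08), while Mgll and Ech1 fell. Of 21 genes of ketone and branched-chain amino acid metabolism, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 8.34e-05; adjusted p = 0.449 with an estimated correlation). Bdh1, which oxidizes ketone bodies, rose by a log2 fold change of 1.23 ± 0.12 and Aldh6a1, of valine breakdown, by 0.94 ± 0.07, and Bckdha fell (-0.29). Of 25 genes of mitochondrial quality control and biogenesis, 12 rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.0151; adjusted p = 0.449 with an estimated correlation). They included the coactivator Ppargc1a (1.08 ± 0.07), the nuclear receptor Esrrg (1.49 ± 0.11) and the fusion proteins Mfn2 (1.01 ± 0.08) and Opa1 (1.03 ± 0.09), and the members that fell were Clpp, Fis1, Sirt4 and Hspe1. Glucose uptake and glycolysis genes were not called (median 0.13; 8 of 23 rose and 5 fell; camera adjusted p = 0.347), though glycogen synthase Gys1 rose (1.07 ± 0.07). Fat-cell markers rose in the same libraries (median 3.25). With genes limited to a mean of at least 5 FPKM, the TCA cycle (adjusted p = 0.0555), fatty acid (0.0709) and quality control (0.0821) lists were no longer called, and the quality control list was also lost in the limma fit of log2(FPKM + 1) (adjusted p = 0.073).

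Of 23 genes of calcium handling and excitation, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00104; adjusted p = 0.449 with an estimated correlation). Besides Atp2a2 (1.05 ± 0.07), the sodium-calcium exchanger Slc8a1 (1.34 ± 0.12), the calcium release channel Ryr2 (1.03 ± 0.09) and the potassium channel Kcnq1 (0.81 ± 0.09) rose, and Kcnip2, a subunit of the transient outward potassium channel, fell (-0.48). Atrial markers rose in the same libraries (10 of 12, median 3.20). The sarcomere list was not called, with 9 of 22 members higher and 8 lower (camera adjusted p = 0.676), and its median of 0.02 had the opposite sign to its mean of -0.04 and its test direction. Its members that fell included the telethonin gene Tcap, from 1637 to 730 FPKM (-1.22 ± 0.08), and the ventricular light chain Myl3 (-0.79 ± 0.07). Cmya5 (1.03 ± 0.08) and the light chain kinase Mylk3 (0.80 ± 0.08) rose. The shortest transcripts of the list were those of Tnnc1 (721 nt, -0.74), Myl2 (889 nt, -0.98), Tnni3 (912 nt, -0.85), Tcap (948 nt) and Myl3 (1125 nt). Those members had its largest falls. Myoz2 (2412 nt), Tpm1 (2890 nt) and Tnnt2 (3330 nt) fell less, and Actc1 (1473 nt), Lmod2 (1976 nt), Mylk3 (3696 nt) and Cmya5 (11850 nt) were among those that rose. How far these changes share the length trend of all tested genes was not tested. Of 14 cardiac stress genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.00154; adjusted p = 0.631 with an estimated correlation), a call that ended when FPKM were rescaled to one sum (adjusted p = 0.0669). Ankrd1, a stretch-responsive muscle protein, rose from 75.2 to 360 FPKM (2.21 ± 0.35, or 1.5 without aged replicate 1), and Fhl1 (1.74 ± 0.23) and the metallothionein Mt2 (1.5 ± 0.11) rose. Nppa, the atrial natriuretic peptide and also an atrial marker, was at 257 ± 25 FPKM in young hearts and at 3101 and 972 FPKM in aged replicates 1 and 2. Its log2 fold change of 2.93 ± 0.52 was 1.82 without aged replicate 1, and its call was lost without young replicate 1 (adjusted p = 0.0581). In the robust edgeR fit, Nppa (adjusted p = 0.128), Ankrd1 (0.0975) and Ucp1 (0.112) did not pass. Nppb did not pass (0.66, adjusted p = 0.314), nor did Myh6 (0.09, adjusted p = 0.273). Nppb was at 1.26 without aged replicate 2 and at -0.38 without aged replicate 1, and Myh6 passed in limma with FPKM rescaled to one sum (0.29, adjusted p = 0.023). Myh7, the slow myosin heavy chain, whose locus overlaps an antisense transcript, fell (-0.35 ± 0.10, adjusted p = 0.0392), a call lost without young replicate 1 (adjusted p = 0.246), young replicate 2 (0.111) or aged replicate 2 (0.0603).

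Of 17 complement genes, 9 rose and none fell (10 and 0 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 9.68e-06; adjusted p = 0.477 with an estimated correlation). C3, the central component, rose from 20.2 ± 0.535 to 96.3 ± 14.1 FPKM, and C4b had a log2 fold change of 2.34 ± 0.18. Of 34 interferon-stimulated genes, 21 fell and 1 rose (26 and 2 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 1.46e-06; adjusted p = 0.661 with an estimated correlation). Antiviral Rsad2 (-1.60 ± 0.15), the signal transducer Stat2 (-1.10 ± 0.12) and Bst2 (-0.91 ± 0.11) fell, and Gbp6 was the member that rose (0.86 ± 0.10). Among the genes with a mean of at least 5 FPKM, the interferon list had 9 members and a median of 0.06 (adjusted p = 0.578). Neither the complement nor the interferon list passed fry (adjusted p = 0.0563 and 0.116). Of 16 macrophage markers, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.00535; adjusted p = 0.665 with an estimated correlation), a call lost without aged replicate 2 (adjusted p = 0.0518) or with a mean of at least 5 FPKM (0.0677). Mertk, a receptor for the uptake of dying cells, was the member that fell (-0.40). Lyve1 (1.03 ± 0.12) and Cd163 (0.89 ± 0.13), both found on resident cardiac macrophages, rose. MHC class I genes were not called (median -0.32; 4 of 16 fell; camera adjusted p = 0.0737), and were called without young replicate 2 (median -0.30, adjusted p = 0.0425) or aged replicate 2 (median -0.55, adjusted p = 0.000102). Their median was -0.03 without aged replicate 1, and they were also called with no expression minimum (adjusted p = 0.0121).

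Most B and plasma cell transcripts were abundant in aged replicate 2 alone, while Ighg2c was at 0.647, 0.49, 5.67 and 30.3 FPKM in young replicates 1 and 2 and aged replicates 1 and 2. Igkc, the kappa light chain constant region, was at 12.9, 12.1, 13.3 and 1057 FPKM in the same order, and Jchain, which joins antibody chains, was at 0.848, 0.900, 1.16 and 38.0 FPKM. The list had a median of 3.92 with 2 of 13 members higher, Ighg2b and Ighg2c (camera adjusted p = 0.0769), a median of -0.40 without aged replicate 2, and a median of 4.84 without aged replicate 1. Of the 13 members, 4 averaged at least 1 FPKM in young hearts. Camera called the list with a mean of at least 0.1 FPKM (2.96, adjusted p = 0.0143) and with no expression minimum (2.94, adjusted p = 0.00259). Igkc and Jchain passed with DESeq2 (adjusted p = 0.0228 and 0.0334). Ighg2b lost its call without aged replicate 2 (1.03, adjusted p = 0.215) or either young library (0.152 and 0.187), and Ighg2c without young replicate 2 (adjusted p = 0.052). MHC class II genes, with 0 of 8 called (median 0.68, camera adjusted p = 0.347), had a median of 1.24 without aged replicate 1 (adjusted p = 5.19e-10) and of -0.15 without aged replicate 2. The largest rises of all genes were variable segments of antibody genes. Ighv1-42 had counts of 0, 0, 6 and 315, at least 114-fold higher by a floor of 3 counts over the young group, and Ighv5-15 and Igkv12-89 were at least 61.8-fold and 51.1-fold higher. These bounds rest on aged replicate 2, since the counts in aged replicates 1 and 2 were 7 and 167 for Ighv5-15 and 12 and 132 for Igkv12-89. These 3 segments, with Ighv1-80, Iglv1 and Igkv12-44, share sequence with relatives, so their single values are uncertain, and all 6 calls were lost without young replicate 1 (adjusted p from 0.0748 to 0.153). T and NK cell markers had 4 of 24 members above the expression minimum and were not tested as a list.

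Fibrillar collagens and interstitial matrix genes were not called (median 0.12; 5 of 32 rose and 1 fell; camera adjusted p = 0.295), but were called without young replicate 2 (median 0.14, adjusted p = 0.0381) or aged replicate 2 (median 0.24, adjusted p = 0.00622), and had a median of -0.09 without aged replicate 1. The collagens Col1a1 (0.18, adjusted p = 0.356) and Col3a1 (0.41, adjusted p = 0.0973) did not pass. Col3a1 did pass with DESeq2 (0.40, adjusted p = 0.0255), with FPKM rescaled to one sum (0.58, 0.0452) and without aged replicate 2 (0.64, 0.000667), and was at 0.11 without aged replicate 1. Ccn2, a matrix protein induced by TGF-beta, rose (1.52 ± 0.21). Matrix-degrading enzymes and inhibitors (median 0.25; 4 of 16 rose and 1 fell; camera adjusted p = 0.148, but 0.0364 with a mean of at least 0.1 FPKM) held a rise of Mmp3 (1.95 ± 0.15) and a fall of the inhibitor Timp4 (-0.80 ± 0.10). Cell cycle genes had 0 of 18 members called (median 0.03, mean -0.03, camera adjusted p = 0.83, direction down), and the proliferation marker Mki67 did not pass (0.08, adjusted p = 0.846). Senescence and p53 target genes were not called (median 0.04; 4 of 17 rose and 2 fell; camera adjusted p = 0.691). Ccng1 (0.93 ± 0.08) rose, Plk2 (-1.15 ± 0.13) fell, and the cell cycle inhibitor Cdkn1a rose (0.47 ± 0.08), with its call lost without young replicate 1 (adjusted p = 0.0665). Cdkn2a stayed below the expression minimum, at 0.0586, 0.939, 1.18 and 1.25 FPKM in young replicates 1 and 2 and aged replicates 1 and 2. Secreted inflammatory factors were not called (median 0.34, 4 of 17 rose and 3 fell, camera adjusted p = 0.717), with Il33 (2.21 ± 0.38) higher and Cxcl12 (-0.88 ± 0.09) lower. The log2 fold change of Il33 was 1.70 without young replicate 2 and 2.97 without young replicate 1.

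Annotation terms were tested among all called genes. Among genes that rose, 40 GO terms were enriched, led by the mitochondrial matrix (68 of 169 genes, 36.4 expected, adjusted p = 2.19e-05), and 19 KEGG pathways, led by insulin signaling (52 of 110). With term sizes of 5 to 200 genes, 13 of 3322 GO terms passed. Among genes that fell, the structural constituents of the ribosome (87 of 155, adjusted p = 1.81e-23) led 41 GO terms, and oxidative phosphorylation (82 of 120, adjusted p = 2.3e-31) led 13 KEGG pathways.

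Tests of single genes were two-sided and adjusted over all tested genes. None of the 23 list calls held with an estimated correlation, for which the smallest adjusted p was 0.449. The fry test asks whether the genes of a list move on balance one way and does not compare them with other genes. It called 16 lists, 14 of them called by camera. Camera calls that fry did not share were complexes II to V (fry adjusted p = 0.0518), complement (0.0563), PPAR targets (0.0805) and ribosomal proteins (0.0863). The others were interferon-stimulated genes (0.116), cardiac stress genes (0.127), macrophage markers (0.127), valve and cartilage-like markers (0.127) and basement membrane (0.197). With 2 libraries an age, an exact permutation test cannot go below p = 0.333, so every call rests on the spread that edgeR shares between genes. Titles of the aged libraries hold the word FLOX, which the young titles lack, although the genotype label is wild type in all 4. A difference in genotype, breeding, batch or dissection that runs with the titles cannot be told apart from age.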

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

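DESeq2, both trend removals and the fit without mitochondrial genes were chosen after the data were seen, and the other settings before. The limma fit of log2(FPKM + 1), planned as the test, was made an alternative after the data were seen, because the table holds counts. Among genes called both in the reported fit and under another setting, only 2, after quantile normalization, were called in the opposite direction. Median-ratio scaling left all 47 lists and all 224 named genes on their side of the threshold, and DESeq2 left 46 lists and 217 genes there. With an estimated correlation, a test with 2 residual degrees of freedom and little power, 23 list calls were lost. No paired analysis was possible because the labels pair no young library with an aged one. In fits without 1 library, the lone sample is assumed to vary like the other group. Depth limits genes near 3 counts. The setting without assembly-made loci was not run, since the table has 0 of them.

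With a mean of at least 5 FPKM, which tests 5549 genes, 1469 rose. With FPKM rescaled to one sum, 3820 rose and 1100 fell. Among changes of at least 1 log2 unit, 383 rose and 311 fell. Terms of 5 to 200 genes gave 13 GO terms among genes higher. Leaving out 1 library gave 1187 to 2514 genes higher and 890 to 2144 lower.

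The following medians and log2 fold changes turned in sign; most lie near 0, and the cause was not tested. At 5 FPKM: sarcomere -0.027, senescence -0.16, secreted factors -0.38, interferon 0.062 and immediate early genes -0.16. Rescaled: imprinted 0.067, pericyte 0.14, Schwann 0.14, proteasome 0.032, Thy1 0.18, the first Nnt entry 0.18 and mt-Co1 0.078. In limma with pseudocount 1, with or without a variance trend, pericyte 0.0082 and Thy1 0.041; with pseudocount 0.1, pericyte 0.003, Thy1 0.048 and Nnt 0.30. At 0.1 FPKM, senescence -0.0047 and Thy1 0.024; with no minimum, -0.0078 and 0.018. After quantile normalization, which gives all libraries 1 set of values, the mitochondrially encoded list 0, mt-Co1 0, mt-Cytb 0.12 and mt-Atp6 0.10. With length removed, sarcomere -0.026 and Thy1 0.048; with GC and length removed, cell cycle -0.025 and Thy1 0.10.

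Without 1 library, ranges crossed 0 for sarcomere (-0.044 to 0.073), collagens (-0.087 to 0.24), cell cycle (-0.20 to 0.22), secreted factors (-0.24 to 0.56), MHC class II (-0.15 to 1.24), B and plasma cells (-0.40 to 4.84), pericyte (-0.15 to 0.0046) and Schwann markers (-0.12 to 0.025), and for Cenpf (-0.23 to 1.06), H2-Eb1 (-0.13 to 1.25), Trbc2 (-6.33 to 4.45), Ccl5 (-1.92 to 2.97), Trac (-0.57 to 2.48), Thy1 (-0.11 to 0.084), Nnt (-2.10 to 2.76), Nppb (-0.38 to 1.26) and Mki67 (-0.25 to 0.47). The low end for Trbc2 was a fitted value with 0 counts in aged replicate 1, so it is not an exact fold change.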

Other observations

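The tests of the range between the aged libraries and of endothelial markers called higher were chosen only after their results were seen, and the settings with length and GC trends removed were added after the data were seen. Of 18 glucocorticoid-responsive genes, 10 rose and 3 fell (11 and 4 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.00154; adjusted p = 0.477 with an estimated correlation). They included Fkbp5, a chaperone of the glucocorticoid receptor (1.19 ± 0.09), and the transcription factors Zbtb16 (1.30 ± 0.08) and Klf15 (0.99 ± 0.08), while Sgk1 (-0.80), Ddit4 and Nfkbia fell. Of 26 autophagy and lysosome genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.00853; adjusted p = 0.449 with an estimated correlation), among them the lysosomal membrane protein Lamp2 (0.75 ± 0.08), while Map1lc3a fell. Of 23 genes of ER stress and the unfolded protein response, 12 rose and none fell (12 and 1 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.011; adjusted p = 0.449 with an estimated correlation), among them the chaperones Hspa5 (0.67 ± 0.07) and Canx (0.51 ± 0.07). The calls of these 3 lists ended at a mean of at least 5 FPKM (adjusted p = 0.057, 0.0673 and 0.059), and that of the glucocorticoid list also with FPKM rescaled to one sum (0.0737). Heat shock genes (median 0.09; 6 of 20 rose and 2 fell; camera adjusted p = 0.295) and proteasome genes with muscle ubiquitin ligases (median -0.17; 4 of 25 rose and 11 fell; camera adjusted p = 0.193, or 0.0476 after quantile normalization) were not called, though Psmb5 fell (-0.58 ± 0.07) and Fbxo40 rose (0.80 ± 0.08).

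Several other lists held single genes that changed. Antioxidant genes (median 0.08; 7 of 26 rose and 6 fell; camera adjusted p = 0.406) held higher Gpx3 (1.68 ± 0.17) and catalase, Cat (0.92 ± 0.08), and lower Sod1 (-0.66 ± 0.07). Clock genes (median -0.23, 4 of 21 rose and 6 fell, camera adjusted p = 0.676, but called without aged replicate 1, median -0.33) held higher Noct (1.23 ± 0.11) and lower Dbp (-1.55 ± 0.31). The log2 fold change of Dbp was -1.13 without aged replicate 2 and -2.15 without aged replicate 1, and its call was lost without young replicate 1. Hypoxia-responsive genes (median 0.22; 7 of 19 rose and 6 fell; camera adjusted p = 0.778) held higher Pdk1 (1.18 ± 0.14) and lower Vegfa, the main growth factor of endothelial cells (-0.90 ± 0.09). TGF-beta and BMP signalling (median 0.25; 7 of 21 rose and 5 fell; camera adjusted p = 0.83) held lower Id1 (-0.98 ± 0.07), and immediate early genes (median 0.18; 5 of 22 rose and 5 fell; camera adjusted p = 0.724) held higher Nr4a3 (2.05 ± 0.33). Imprinted growth genes (median -0.12; 2 of 12 rose and 5 fell; camera adjusted p = 0.406) held higher Gpc3 (1.54 ± 0.18) and lower Cdkn1c (-1.05 ± 0.12). Neutrophil and mast cell markers (median -0.60; 6 of 13 fell; camera adjusted p = 0.138, or 0.0144 with FPKM rescaled to one sum) held lower Ltf (-0.99 ± 0.14). Erythroid markers (median 0.58; 7 of 11 rose and 2 fell; camera adjusted p = 0.0737) were called higher under 7 other settings, among them DESeq2 (adjusted p = 0.0149) and the fit without young replicate 1 (0.0412), and held higher Hba-a2 (0.71 ± 0.08) and Hbb-bt (0.74 ± 0.09), which share reads with near-identical copies. Skeletal muscle and other thoracic markers were not called (median -0.40; 1 of 8 rose and 3 fell; camera adjusted p = 0.516).

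Xist, which silences an X chromosome in females, was at 21.9, 20.7, 11 and 12.5 FPKM in young replicates 1 and 2 and aged replicates 1 and 2 (log2 fold change -0.91 ± 0.09, adjusted p = 0.00156). The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at no more than 0.178 FPKM in any library, and the list of Y-linked and X-inactivation genes, with 1 of 10 members above the minimum, was not tested. Whether X-linked output was higher with lower Xist was left open, since the median of 363 X-linked genes exceeded that of autosomal genes by 0.075 (permutation test, p = 0.0138), short of the difference of 0.1 set for that reading. The permutation moved genes between groups, so its p treats genes as independent and does not measure the spread between samples. Medians of single autosomes ran from -0.098 (chromosome 7) to 0.107 (chromosome 18), a range that holds the X (0.073). Nnt, which is partly deleted in C57BL/6J mice, stands on 2 overlapping entries whose log2 fold changes of -1.14 (adjusted p = 0.48) and 1.06 (adjusted p = 0.0644) did not pass. Without young replicate 1 or 2, the first entry was at 2.76 or -2.10 and the second at 0.57 or 1.82. The second passed in limma with FPKM rescaled to one sum (1.39, adjusted p = 0.0481). Of the counts of both entries, the first held 54.5% in young replicate 1 and 1.71% to 7.86% in the other libraries. Their summed counts were 226 and 249 CPM in the young libraries and 399 and 385 CPM in the aged, a difference larger than the spread within either age and not tested by the fit.

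The list medians of atrial, mesothelial and fat-cell markers were 3.20, 2.06 and 3.25 among genes above the expression minimum, which a rise helps a gene to pass. Most of these markers were higher in both aged hearts. Whether both held 1 same mix of extra tissue was left open, since the log2 ratio of aged replicate 1 to aged replicate 2 spanned 3.86 over called atrial and fat-cell markers without Bmp10, and 7.93 with it. Fat-cell markers other than Ucp1 (2.47) had ratios of -1.39 to 0.11. Atrial markers other than Bmp10 (-5.46) and Upk3b (-0.03) had ratios of 0.24 to 1.71. Second lists of these 2 kinds were read in the fit with no expression minimum, which called 1977 of 28723 genes higher. The first lists were read in the reported fit, which called 2416 of 12027 higher, so the counts of calls are not on one footing. In a second list of 8 atrial genes, 7 were called higher with a median of 1.56, which is consistent with more atrial tissue in the aged samples but could also come from atrial genes switched on in other muscle. In a second list of 8 fat-cell genes the median was 1.35 but 3 were called higher and Aqp7 lower, so added fat tissue cannot be told apart from changes in single genes. How the hearts were dissected and age itself stay open, untested.

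Of 26 endothelial markers 21 fell, and the list median was -0.89. With GC and length trends removed the median was -0.86, but that test could hardly come out otherwise. Endothelial markers had a median length of 3432 nt and a median GC content of 52.4%, close to the 3096 nt and 50.1% of all tested genes. Over all tested genes, the lowest median of a length bin was -0.35, and the genes with the highest GC content had a median of -0.15. Trends of that size are too small to be the whole cause. A lower share of every kind of endothelial cell stays open: 4 endothelial markers were called higher, but added atrial tissue, which was not excluded, would bring endothelium of its own. Lower expression per cell and age stay open too, and neither was tested.

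Most nuclear genes of the respiratory chain fell, with medians of -0.74 for complex I and -0.71 for complexes II to V. Short transcripts were lower at 12 months in general, but with the length trend removed the medians stayed at -0.59 and -0.53. With GC and length removed complex I stayed at -0.64, so the trends as fitted here do not account for the whole fall. A part of the fall may still be shared with the length trend, given the move from -0.74 to -0.59. The fit cannot exclude a larger part, because it used the longest listed transcript of each gene. By that measure, the complex I members of 2020 nt or more were mixed. Ndufb2 (4371 nt, -1.14), Ndufb7 (4435 nt, -1.04), Ndufv3 (2021 nt, -1.03) and Ndufb8 (2142 nt, -0.72) fell. Ndufs1 (2661 nt, 0.64) rose, and Ndufa10 (2020 nt, -0.02) and Ndufb5 (3127 nt, -0.26) did not pass. Whether the longest listed transcript is the one expressed was not tested, so these members do not decide the part of length. Age, and a handling difference that acts on transcripts of respiratory chain genes beyond their length, stay open and were not tested.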
